A study of Mus musculus with 4 samples.

How the data were processed

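Gene expression was measured by RNA sequencing in 4 libraries of HT-22 cells, an immortalized mouse hippocampal neuronal cell line: 2 from control cells, called uninduced in the samples' characteristics and wild type in their titles, and 2 from cells in which Pja2 was induced by means the labels do not give. The titles of the induced samples read Pja2-pb, a tag that the labels do not explain. Per the labels' protocols, RNA was extracted with Trizol, libraries were made with a TruSeq RNA kit, which does not mark the strand, and cells were at passages 21 to 24. The submitters' processing notes name HISAT and Cufflinks, without versions, and the genome build mm9. The tool that counted reads per gene and the scaling between libraries are not given in the sources used here.

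The deposited table holds log2 values for 24689 Ensembl mouse genes with a symbol each, in 4 columns matched to the samples by the samples' descriptions. The unit was settled from the values. With 2 raised to each value and 1 subtracted, 100% of the values in every library were whole multiples of 1 step per library, within a tolerance of 0.01 (largest distance 0.000774). The deposited log2 values are therefore log2(normalized read count + 1), and the whole reads behind them could be recovered. Values of this kind are called normalized reads here. The recovered totals were 25787452 and 31010351 reads in the controls and 30080376 and 35262653 in the induced cells. CPM denotes reads scaled by these totals, and 1 CPM stood for 25.8 to 35.3 reads. The library steps lay within 0.996 to 1.00 times the reciprocals of the factors that the median-of-ratios method gives, up to a constant common to all libraries. The design fixed before the data were examined had foreseen FPKM values or plain counts. As the values are on the log2 scale, limma with a trend, which the design named for log2 FPKM, was used, with the filter set on CPM in place of FPKM. The quasi-likelihood count model that the design named for plain counts was not run, although whole reads could be recovered, and limma voom on those reads stands as the check on counts.

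Fold changes were tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values, which carry a pseudocount of 1, so that the change of genes with few reads is understated on that scale. Genes with a mean of at least 1 CPM over the 4 libraries were kept, which left 13276. The fit held both groups and no covariate, the variance prior followed a trend on expression, and p-values are two-sided. Every adjusted p given for a gene is limma's with Benjamini-Hochberg adjustment over the 13276 genes, with a threshold of 0.05. A fold is the ratio of the groups' mean normalized reads, and a log2 fold change is the difference of the groups' mean log2 values, induced minus control. Where all libraries of a group were at 0, the fold is a lower bound against 3 reads per library. Where a group held 1 to 3 reads, an exact binomial interval of the ratio is given. These intervals and bounds cover counting error only.

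Before the data were examined, 47 gene lists were fixed (pathways, complexes and cell type markers), and 42 of them had at least 5 tested members. Each was tested with camera (limma) with a preset correlation between genes of 0.01, adjusted over the 42 lists, and again with the correlation estimated from the residuals, a test that rests on 2 residual degrees of freedom. A list's median was also set against 10000 random lists of the same size matched on expression. Counts given as adjusted over the list alone used Benjamini-Hochberg adjustment within that list only, with none across the 42 lists. Members counted that way as rising or falling are not calls over all tested genes. The rule for the genes named was fixed at the same time: Pja2, Pja1, P2rx3 and P2rx7 whatever their values; the 10 largest rises and 10 largest falls past the threshold, leaving out predicted models, short RNAs and genes absent from a group; and in each list up to 4 members past the threshold by size of change, with up to 2 others of highest expression. Genes named outside the rule are marked as such.

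On simulated libraries with the real genes' means, in which 200 of 13276 genes were changed in the comparison of induced with control cells, limma recovered 54% of the 2-fold and 86% of the 4-fold changes, with 6.04% of its 149 calls false. A list shifted by -0.5 was found in 20 of 20 simulated runs. The simulated genes were drawn independently of one another, so these runs do not show how the set test behaves where members vary together. The search for stretches of neighbouring genes was tested on shuffled values of 13219 genes with a run of 100 genes raised by 0.5, and found 95 of them. The replicates of a group differed beyond counting noise (chi-square per gene of 18.3 in the controls and 14.0 in the induced cells), so none is a second copy of another. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

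Chromosomes, gene order, exon lengths, GC content and exon overlaps between genes came from GENCODE mouse release 21, which is on a later build than mm9. Of the listed identifiers 24591 (99.6%) were found in it, and no coordinates are given because the builds differ. Genes whose exons overlap those of another gene are pointed out, since unstranded reads of such pairs cannot be told apart. The alternatives fixed before the data were examined were the replicate number as a block, no filter, a filter of 5 CPM in the higher group, a pseudocount of 0.1, centring of the libraries, a minimum of 2-fold, the estimated correlation and leaving out each library. Added after the data were seen were limma voom on the recovered reads, removal of a loess trend on gene length and GC content, and fits without chromosome 16 or without genes with overlapping exons. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.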

Results

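RNA from HT-22 cells was sequenced in 4 libraries, 2 from uninduced control cells and 2 from cells induced to express Pja2. Pja2 encodes a RING-type E3 ubiquitin ligase known to act on regulatory subunits of protein kinase A. The libraries held 25787452 and 31010351 reads in genes for the controls and 30080376 and 35262653 for the induced cells. Between 20494 and 21289 genes had at least 1 read per library. The sources used here call the controls both uninduced and wild type, so it is not known whether both groups came from 1 line, and any comparison may hold differences between lines. Values are normalized reads, given as mean ± SD with n = 2 per group. The series title names the receptors P2rx3 and P2rx7 as an axis of Pja2 action, so these genes are reported before all others.

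Pja2 (ENSMUSG00000024083, chromosome 17) rose 9.05-fold, from 6024 ± 202 normalized reads in control cells to 54537 ± 415 in induced cells. P2rx7 (ENSMUSG00000029468, chromosome 5), an ATP-gated cation channel, rose 2.06-fold, from 154 ± 0.645 to 318 ± 15.9. P2rx3 (ENSMUSG00000027071, chromosome 2), another ATP-gated channel, had 62.8 ± 5.42 in controls and 27.7 ± 14.6 in induced cells and did not pass the test. Pja1 (ENSMUSG00000034403, chromosome X), the closest relative of Pja2, had 983 ± 783 and 935 ± 661, with libraries of each group far apart: 1537 and 429 in the controls, 1403 and 467 in the induced cells. The limma log2 fold changes were 3.18 (SE 0.06, adjusted p = 6.36e-05) for Pja2 and 1.04 (SE 0.14, adjusted p = 0.0249) for P2rx7. They were -1.25 (SE 0.43, adjusted p = 0.201) for P2rx3 and -0.00 (SE 0.72, adjusted p = 0.998) for Pja1. The P2rx7 call was lost without the expression filter (adjusted p = 0.052) and when any of the 4 libraries was left out (0.0607 to 0.0964), while its log2 fold change stayed between 0.99 and 1.09, and its exons overlap those of the microRNA gene Mir8115. For P2rx3 the log2 fold change was -0.71 without induced replicate 1, it rested on 109 and 57 reads, and its exons overlap those of Ssrp1, which had 10799 and 10666 normalized reads (named after its values were seen).

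**Figure D1:**
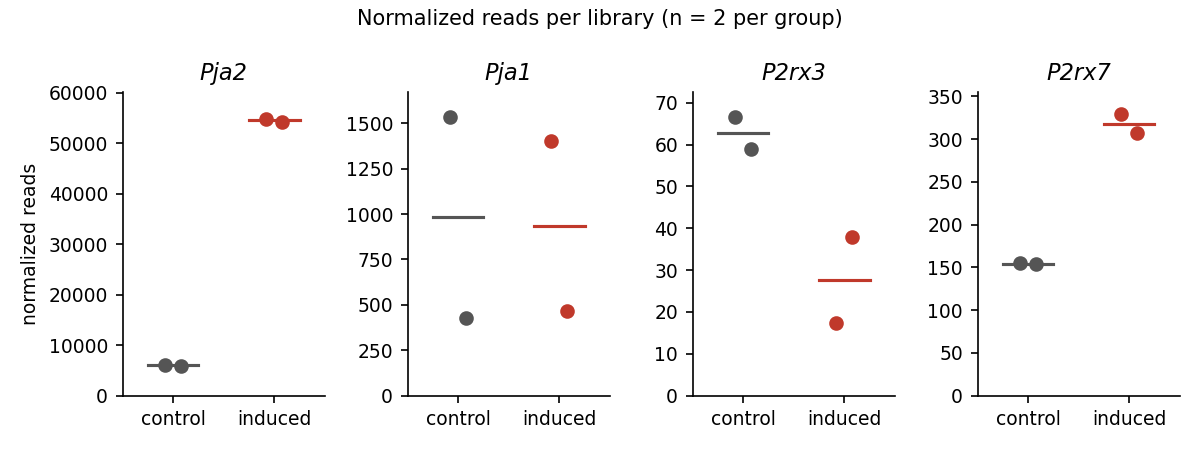
Normalized reads (vertical axes, from 0, a scale per gene) of Pja2, Pja1, P2rx3 and P2rx7 in control and induced cells, with a point per library and a line at the mean of 2 libraries. Pja2 lies near 6024 in controls and 54537 in induced cells, P2rx7 near 154 and 318, and the libraries of Pja1 are split within both groups.

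Among the 8 tested purinergic receptors, P2rx7 was the 1 that rose and none fell, and the count adjusted over the list alone was the same 1 rise. P2rx4, the most abundant, had 1427 ± 32.6 and 1318 ± 32.6 (adjusted p = 0.473), and P2rx5 had 241 ± 20.4 and 217 ± 44.9 (adjusted p = 0.694). The list as a whole did not pass the set test (adjusted p = 0.747). Of 9 tested ectonucleotidases and adenosine-handling genes, Entpd5, a nucleoside diphosphatase of the endoplasmic reticulum, rose 2.22-fold (adjusted p = 0.0226), 0 fell, and the list did not pass (adjusted p = 0.683). The Entpd5 call ended when 3 of the 4 libraries were left out in turn (adjusted p up to 0.0600).

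Of 30 tested genes of protein kinase A and cAMP signalling, the regulatory subunit gene Prkar2b fell (1604 ± 63.6 to 1119 ± 5.39, adjusted p = 0.0312) and the adenylyl cyclase gene Adcy7 rose 1.40-fold (adjusted p = 0.0306). The other 28 did not pass, and neither did the list (adjusted p = 0.896). Of 30 tested calcium genes, the store sensor Stim1 rose 1.51-fold and the plasma membrane pump Atp2b1 rose 1.34-fold, while the calcineurin subunit Ppp3cb fell from 3802 ± 50.8 to 2677 ± 50.8 (adjusted p = 0.0226, 0.0353 and 0.0214). The calcium list did not pass (adjusted p = 0.588), nor did phospholipase C and protein kinase C, with 0 of 10 members called (adjusted p = 0.788). Of 49 tested RING-family ligases, Rnf168 and Mdm2 rose and Rnf130 fell (adjusted p = 0.0312, 0.0451 and 0.0102), and the list did not pass (adjusted p = 0.588). Leaving out a single library ended the calls of Prkar2b, Adcy7, Stim1, Atp2b1 and Ppp3cb (adjusted p up to 0.107, 0.107, 0.0883, 0.132 and 0.0776) and of Rnf168 and Mdm2 (up to 0.121 and 0.171). Without the expression filter only Ppp3cb and Rnf130 kept theirs.

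Across the transcriptome, 276 genes were higher and 178 lower in induced cells among 13276 tested, and 69 and 70 of them differed at least 2-fold. All 454 had both induced libraries on the same side of both controls, which 51.3% of all tested genes showed and chance gives 33.3%. The largest rises under the naming rule were those of Acp5 (39.7 ± 20.4 to 555 ± 14.1, log2 fold change 3.87), a lysosomal acid phosphatase, and of the membrane protein gene Ms4a4d (14.1-fold, 88.5 ± 5.96 to 1244 ± 2.61). Mgam, a maltase-glucoamylase, rose 9.79-fold from 14 reads in the controls, and its log2 fold change ran from 2.72 to 3.70 over the refits. The secreted guidance cue Sema3c rose 6.77-fold (1112 ± 300 to 7526 ± 140), and Cd80, a co-stimulatory ligand of T cells, 6.65-fold. Col12a1, Chil1, Ces2g and Slc43a2 followed at 5.66, 5.56, 5.01 and 4.51-fold. Aox3, an aldehyde oxidase, fell from 3668 ± 403 to 8.83 ± 3.26, the lowest log2 fold change of all on the scale with a pseudocount of 1 (-8.58, SE 0.26, adjusted p = 0.000423). Cyp3a41a fell from 427 reads in the controls to 1 read, a ratio of means beyond that of Aox3 with a wide interval (87.3 to 19357), and Cyp2b13 had a ratio interval of 26.2 to 801. Both are cytochrome P450 genes with close relatives that can share reads, so their values are uncertain. Shroom1, Tnik, Masp1, Il2rg, Dpt and Dyrk4 also fell, with log2 fold changes of -4.12, -4.00, -3.75, -3.72, -3.44 and -3.37. Acp5, Slc43a2, Shroom1 and Il2rg have exons that overlap another gene. The adjusted p of the genes named here ranged up to 0.0491 for Il2rg. The omission of 1 library ended the calls of Mgam, Ces2g and Slc43a2 (adjusted p up to 0.0896, 0.112 and 0.0952) and of Cyp2b13, Shroom1, Tnik, Il2rg and Dyrk4 (up to 0.0664, 0.0652, 0.108, 0.138 and 0.0696).

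The counts of called genes fell whichever library was left out. Such fits have fewer residual degrees of freedom, so dependence on a library and lost power cannot be told apart. A block on the replicate number, which removed no library, also lowered the counts, to 157 higher and 104 lower. The higher genes numbered 126 and 113 without induced replicate 1 or 2, and the lower genes 78 and 111 without control replicate 1 or 2. Without the expression filter 100 were higher and 59 lower. Of 91 named genes past the threshold, 33 passed it in every refit counted here in which they were tested. Among them were Pja2, Acp5, Ms4a4d, Sema3c, Aox3, Slc7a11, Ptgs2 and Cdkn1a. Left aside were the minimum of 2-fold, which is no refit, and the fits without chromosome 16 or without overlapping-exon genes.

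**Figure D2:**
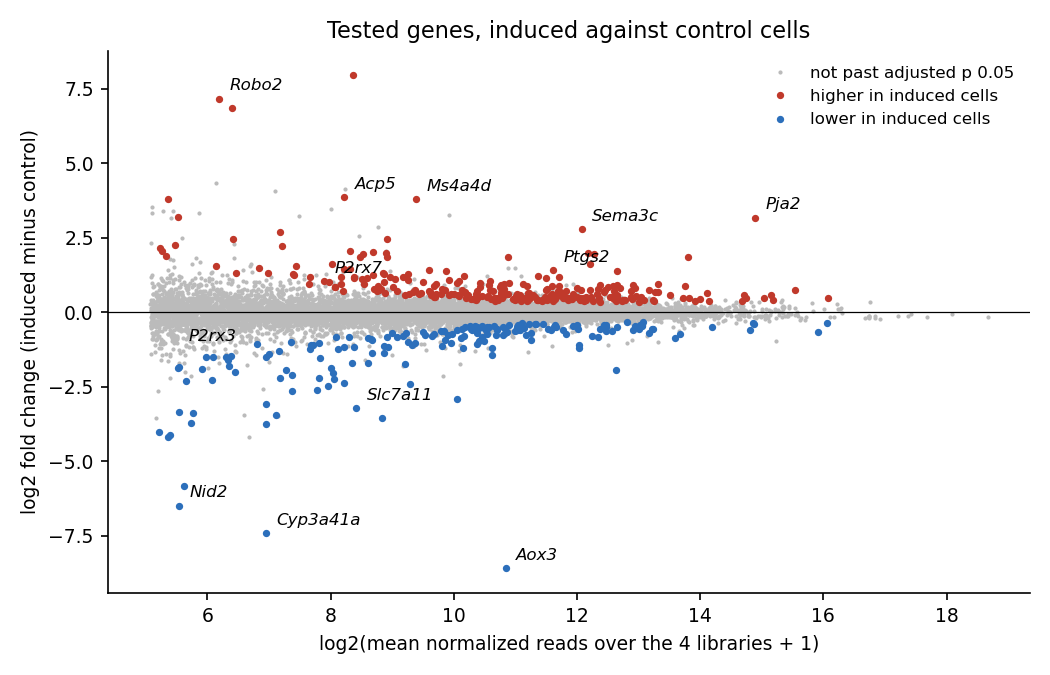
The log2 fold change (induced minus control) of the 13276 tested genes against log2 of their mean normalized reads + 1, with 276 higher genes in red, 178 lower genes in blue and the others in grey. Pja2 stands apart at 3.18 among abundant genes, Aox3 lies lowest at -8.58, and P2rx3 is grey.

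Of 23 tested genes of cholesterol synthesis and uptake 8 fell, 0 rose and 15 did not pass, and all 23 had a log2 fold change below 0, with a median of -0.48. The set test gave an adjusted p of 3.74e-16, and the adjusted p was 0.519 with an estimated correlation. Adjusted over the list alone, 19 of the 23 fell. Insig1, a sterol-regulated brake on the pathway, fell from 6151 ± 24.2 to 3591 ± 266. Fdps, which makes farnesyl diphosphate, fell by 0.70 on the log2 scale and the squalene epoxidase gene Sqle by 0.57. Srebf2, the transcription factor gene of the pathway, had a log2 fold change of -0.33 and Hmgcs1 of -0.49, short of the threshold (adjusted p = 0.0509 and 0.0596). In fatty acid synthesis 3 of 16 members fell and 0 rose, with a median log2 fold change of -0.21 (set test adjusted p = 3.44e-05; adjusted p = 0.519 with an estimated correlation). Those were the desaturase genes Scd1 (9213 ± 71.7 to 6102 ± 171) and Scd2 and the elongase gene Elovl6, and adjusted over the list alone 8 fell. Fasn and Acly had log2 fold changes of -0.25 and -0.29 (adjusted p = 0.169 and 0.0836). Fits without 1 of the libraries ended the calls of Sqle, Scd2 and Elovl6 (adjusted p up to 0.103, 0.261 and 0.106), and leaving out the filter ended that of Fdps. The exons of Fdps, Hmgcs1, Scd2 and Elovl6 overlap another gene.

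Of 23 tested p53 target genes 9 rose, 0 fell and 14 did not pass, 5 lay below 0, and the median log2 fold change was 0.41. The set test gave an adjusted p of 1.06e-05, and the adjusted p was 0.519 with an estimated correlation. Adjusted over the list alone, 13 rose and 1 fell. The death receptor gene Fas rose 2.05-fold (712 ± 87.6 to 1458 ± 58.3), the antiproliferative gene Btg2 2.02-fold, Trp53inp1 1.84-fold, and the cyclin-dependent kinase inhibitor gene Cdkn1a 1.72-fold (3801 ± 292 to 6540 ± 232). Mdm2, the ubiquitin ligase of p53, rose 1.33-fold. Zmat3 had a log2 fold change of 0.68 and an adjusted p of 0.0528. Btg2 and Mdm2 kept their calls in 8 and 5 of the 11 refits counted, and leaving out a single library ended both. Their log2 fold changes ran from 0.89 to 1.13 and from 0.35 to 0.47. The exons of Cdkn1a overlap another gene.

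In several lists of growth genes most members lay to the same side of 0 by small amounts and few were called, and none of these lists passed with an estimated correlation. Cell cycle and mitosis genes had a median log2 fold change of 0.12, with 27 of 34 above 0, and Kif20a, a mitotic kinesin gene, was the 1 called, rising 1.37-fold (its exons overlap Cdc23). DNA replication genes had a median of 0.13, with 26 of 31 above 0, and Mcm4 and Tyms rose 1.41-fold and 1.33-fold. Proteasome subunits had a median of 0.13, with 27 of 31 above 0 and 0 called. The set test gave these lists adjusted p-values of 0.000426, 0.00183 and 0.000742, and with an estimated correlation the adjusted p was 0.819, 0.728 and 0.928. Adjusted over the list alone, 6, 5 and 2 members rose and 0, 1 and 0 fell. Cytosolic ribosomal proteins had a median of -0.13, with 38 of 42 below 0, while their 1 called member, Rpl24, rose 1.38-fold. Mitochondrially encoded genes had a median of -0.15, with 13 of 13 below 0 and 0 called. These genes held 5.08% and 5.22% of the reads of the controls and 4.62% and 4.46% of those of the induced cells. The set test gave adjusted p = 2.41e-05 for ribosomal and 0.000372 for mitochondrial genes, against an adjusted p of 0.851 and 0.728 with an estimated correlation. Adjusted over the list alone, 0 members of either changed. Leaving out a single library ended the calls of Kif20a, Mcm4, Tyms and Rpl24 (adjusted p up to 0.122, 0.0674, 0.163 and 0.157), and the exons of Rpl24 overlap another gene.

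The medians of these lists moved with single libraries. Without control replicate 1 the median log2 fold change of proteasome subunits was 0.04 and their call ended (adjusted p = 0.317), and those of cell cycle and DNA replication genes were 0.07 and 0.05. Without control replicate 2 the medians of proteasome, cell cycle and ribosomal protein genes were 0.24, 0.19 and -0.06. Without induced replicate 2 the call of the mitochondrially encoded genes ended (adjusted p = 0.0529).

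Among 23 tested NF-kB and cytokine genes 7 rose, 0 fell and 16 did not pass, and 8 lay below 0 (median log2 fold change 0.25, set test adjusted p = 0.000426; adjusted p = 0.519 with an estimated correlation). Adjusted over the list alone, 12 rose and 1 fell. The iron-binding lipocalin gene Lcn2 rose 2.97-fold, the cyclooxygenase gene Ptgs2 2.67-fold (1699 ± 232 to 4537 ± 244), the inducible nitric oxide synthase gene Nos2 2.25-fold and Nfkbiz 1.96-fold. Csf1 and Vcam1, the other members named, had log2 fold changes of 0.11 and -0.26 (adjusted p = 0.368 and 0.182). Of 21 TGF-beta response genes 5 rose, 0 fell and 16 did not pass (median 0.29, set test adjusted p = 3.44e-05; adjusted p = 0.519 with an estimated correlation), and adjusted over the list alone 11 rose and 0 fell. Among them were Skil at 2.47-fold, Acta2, a smooth muscle actin gene, at 2.27-fold and Ltbp1 at 1.57-fold. The omission of 1 library ended the calls of Lcn2, Nos2, Acta2 and Ltbp1 (adjusted p up to 0.0765, 0.0681, 0.109 and 0.0838), and the exons of Vcam1 overlap another gene. The TGF-beta median was 0.47 with the filter of 5 CPM and 0.49 without overlapping-exon genes.

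Interferon-stimulated genes did not pass as a list (39 tested, adjusted p = 0.896), although Oasl1, Gbp7 and Cxcl10 rose 2.93, 2.16 and 1.64-fold, each with exons that overlap another gene. Of 9 class I histocompatibility genes 1, H2-T23, fell (93.7 ± 22.3 to 24.2 ± 5.06), a family in which copies can share reads. That list passed (median -0.22, set test adjusted p = 0.0143; adjusted p = 0.728 with an estimated correlation), and adjusted over the list alone 3 fell and 0 rose. Fits without 1 of the libraries ended the calls of Oasl1, Gbp7, Cxcl10 and H2-T23 (adjusted p up to 0.157, 0.0621, 0.202 and 0.138). The call of the class I list ended without control replicate 1 (median -0.12, adjusted p = 0.175) and with the filter of 5 CPM (adjusted p = 0.0725).

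Among 27 NRF2 target and glutathione genes 5 rose and 2 fell. The quinone reductase gene Nqo1 rose 1.87-fold (4491 ± 307 to 8414 ± 664) and the peroxiredoxin gene Prdx1 rose by 0.57 on the log2 scale, whereas Slc7a11, the cystine transporter gene, fell from 615 ± 64.1 to 66.3 ± 12.4 and Osgin1 from 284 ± 24.5 to 122 ± 30.9. The list passed upward with a median of 0.25 (set test adjusted p = 0.000105; adjusted p = 0.728 with an estimated correlation), and adjusted over the list alone 14 rose and 2 fell. The 26 genes of the ATF4 and amino acid response had a median of -0.14, with Slc7a11 and the tryptophanyl-tRNA synthetase gene Wars falling and Sesn2 rising. Their set test gave an adjusted p of 0.00410, and the adjusted p was 0.819 with an estimated correlation. Adjusted over the list alone 4 fell and 1 rose. Of 15 ERK feedback genes Spred2 fell by 0.50 on the log2 scale and 0 rose (median -0.31, set test adjusted p = 0.00410; adjusted p = 0.519 with an estimated correlation), and adjusted over the list alone 5 fell and 1 rose. Prdx1, Osgin1, Wars, Sesn2 and Spred2 kept their calls in 10, 6, 6, 5 and 5 of the 11 refits counted. The omission of a single library ended each of these calls. Their log2 fold changes ran from 0.51 to 0.63, -1.49 to -0.97, -0.64 to -0.51, 0.41 to 0.48 and -0.57 to -0.44. The call of the ATF4 list ended without control replicate 2 (median -0.04, adjusted p = 0.290), and its median was -0.23 without control replicate 1. That of the ERK feedback list ended without overlapping-exon genes (median -0.24, set test adjusted p = 0.0724), and its median was -0.17 without induced replicate 2.

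In all, 14 of the 42 lists passed the set test with the preset correlation, 7 up and 7 down. With an estimated correlation 0 passed, and 3 had an unadjusted p under 0.05.

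**Figure D3:**
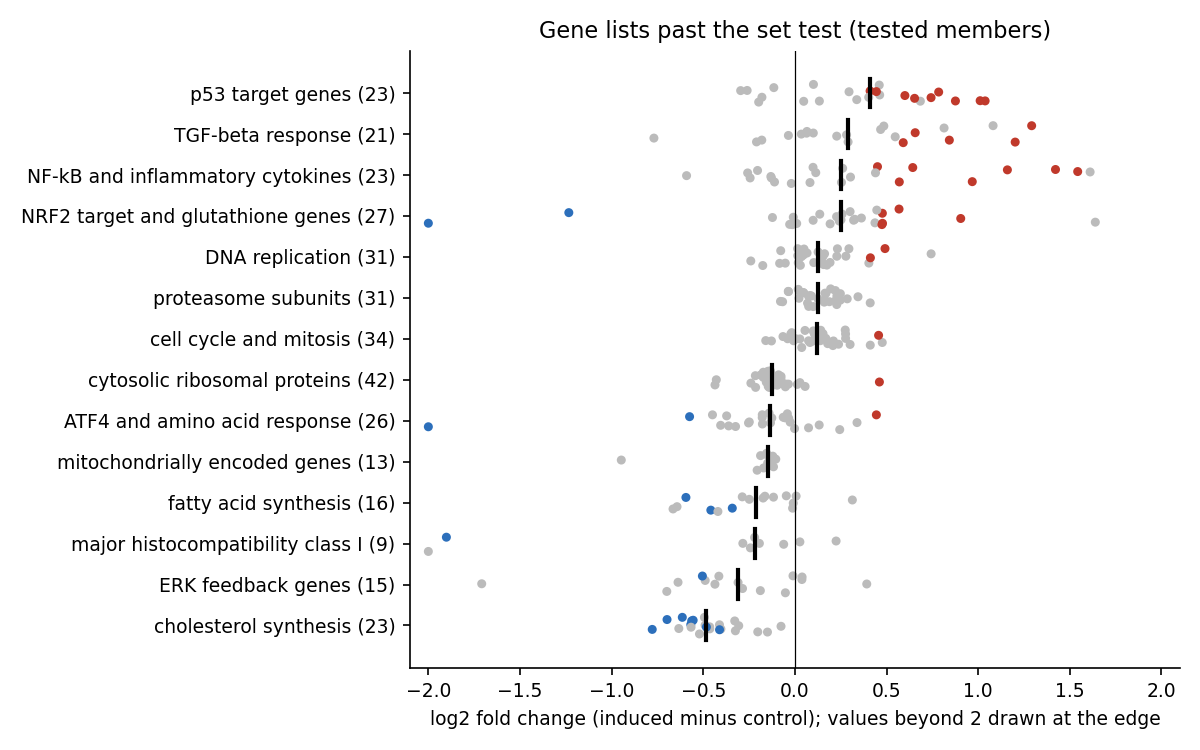
The log2 fold change (horizontal axis, induced minus control) of each tested member of the 14 lists past the set test, with genes past the threshold in red (higher) or blue (lower), the others in grey, and a black bar at the list's median. The medians run from -0.48 for cholesterol synthesis to 0.41 for p53 targets, and values beyond 2 are drawn at the edge.

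Of 37 tested extracellular matrix genes 7 rose and 7 fell, and the list did not pass (adjusted p = 0.249, median 0.12, mean -0.13). Nid2, a basement membrane nidogen gene, fell from 90.7 ± 30.0 to 0 reads, at least 30.0-fold lower, with exons that overlap another gene. Col12a1 rose, while the proteoglycan gene Dcn fell from 907 ± 201 to 276 ± 75.9 and Col5a3 from 1217 ± 139 to 641 ± 13.2. The abundant Col1a2 and Fn1 had log2 fold changes of -0.07 and 0.34 (adjusted p = 0.691 and 0.182). Of 13 matrix proteases and their regulators 2 rose and 3 fell, with Adamts5 going from 5853 ± 1146 to 2523 ± 98.9, Adamts1 from 1802 ± 118 to 869 ± 13.6, and Plau falling (list adjusted p = 0.728). Leaving out a single library ended the calls of Nid2, Dcn and Plau (adjusted p up to 0.0582, 0.0676 and 0.117), and the exons of Fn1 overlap another gene.

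Of 30 axon guidance genes 3 rose and 1 fell (list adjusted p = 0.187). Robo2, the receptor gene of Slit ligands, had 0 reads in both controls and 144 ± 22.1 in induced cells, at least 41.5-fold higher. Plxnb1 rose 2.79-fold and Plxna4 fell from 122 ± 8.30 to 43.3 ± 4.34. YAP/TAZ targets did not pass as a list (19 tested, adjusted p = 0.692): Ctgf, Cyr61 and Ankrd1 fell by 0.67, 0.64 and 0.44 on the log2 scale, and Foxf2 rose 1.69-fold. Of 29 immediate early genes 3 rose and 2 fell (list adjusted p = 0.956): Klf4, Junb and Btg2 rose 1.53, 1.60 and 2.02-fold, and the larger of the falls was that of Arc, from 71.5 ± 12.1 to 19.1 ± 2.15. Among channels Scn3a, a sodium channel gene, fell from 440 ± 111 to 90.7 ± 6.80. The omission of 1 library ended the calls of Plxna4, Ctgf, Cyr61 and Ankrd1 (adjusted p up to 0.106, 0.0553, 0.0734 and 0.177) and of Junb, Btg2 and Arc (up to 0.0648, 0.0813 and 0.133). The exons of Plxnb1, Plxna4, Ctgf, Foxf2 and Junb overlap another gene.

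Markers of cell types set the background of these comparisons. Of 21 neuron markers 3 passed the expression filter, with Eno2 at 4036 ± 101 and 3643 ± 333 and Tubb3 at 598 ± 34.3 and 720 ± 11.9 (adjusted p = 0.386 and 0.229). Of 21 fibroblast and mesenchymal markers 18 passed it, with Acta2 and Des rising and Dcn and Col3a1 falling, and the list did not pass the set test (adjusted p = 0.896). The most abundant of these markers, Col1a2, had a mean of 5406 CPM over the 4 libraries, against 118 CPM for Eno2, the most abundant neuron marker. Fits without 1 of the libraries ended the calls of Acta2, Des, Dcn and Col3a1 (adjusted p up to 0.109, 0.0970, 0.0676 and 0.0858), and the exons of Des and Col3a1 overlap another gene. Microglia and macrophage markers had 0 of 6 members called and did not pass (adjusted p = 0.187), with 5 of 6 above 0 and a median log2 fold change of 0.57, the highest of the 42 lists. Astrocyte markers had 0 of 5 called (adjusted p = 0.896). Oligodendrocyte, endothelial and epithelial markers had 3, 2 and 2 tested members, too few for the set test.

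Of the 276 higher genes 85 (30.8%) lie on chromosome 16, which holds 403 of the tested genes, and 6 of the lower genes do. They fall in a run of 327 tested genes from Zfp263 to Hspa13, in which 85 rose and 4 fell, with a median log2 fold change of 0.37 against 0.06 for the 76 tested genes of that chromosome beyond it. Cd80, Robo2, Nfkbiz, Mcm4, Rpl24, Rnf168 and Psmd2 lie in this run and Masp1, which fell, does too, while Adamts1 and Adamts5 lie beyond it. Mcm4, Rpl24 and Rnf168 kept their calls in 9, 5 and 5 of the 11 refits counted, and leaving out a single library ended each. Their log2 fold changes ran from 0.46 to 0.52, 0.39 to 0.54 and 0.38 to 0.45. Without chromosome 16, a setting added after the data were seen, 170 genes were higher and 154 lower, and 14 lists passed the set test.

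**Figure D4:**
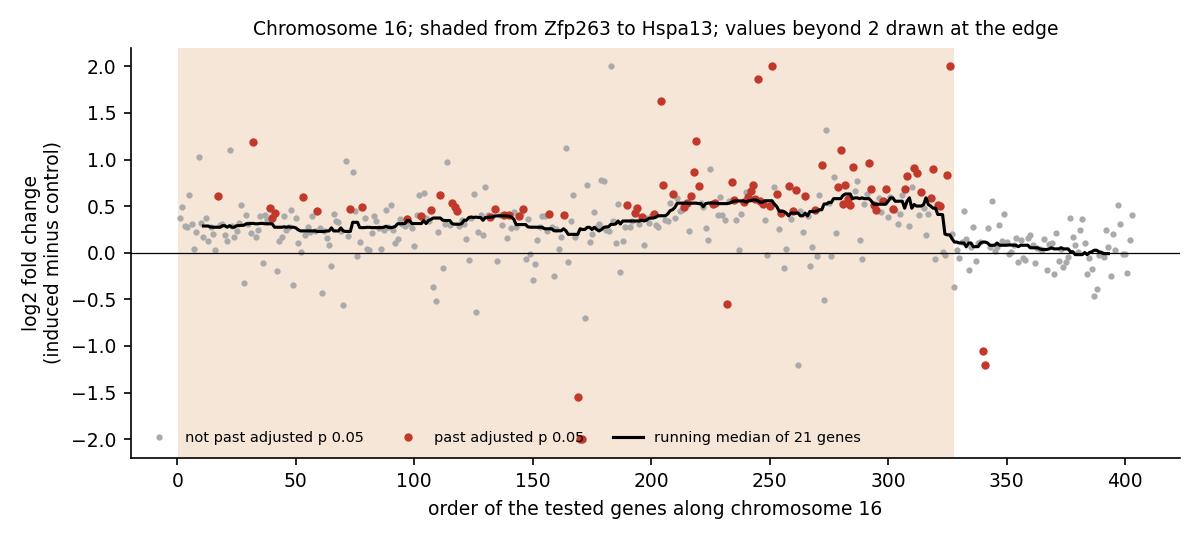
The log2 fold change (vertical axis, induced minus control) of the 403 tested genes of chromosome 16 in their order along it (horizontal axis), with genes past the threshold in red, a running median of 21 genes as a black line and the run from Zfp263 to Hspa13 shaded. The running median stays above 0 through the shaded run and returns near 0 after Hspa13, and values beyond 2 are drawn at the edge.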

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

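The fits with voom, the length and GC trend, and those without chromosome 16 or overlapping-exon genes were chosen after the data were seen. Pja2 kept its direction and call in every refit (3.14 to 3.21), and P2rx3 stayed short of the threshold (adjusted p 0.0997 to 0.497). P2rx7, at 1.04, lost its call without the filter, where 24689 genes share the adjustment, and when any library was left out (0.99 to 1.09), where fewer samples remain and a lone library is assumed to vary like the rest. Against 276 higher and 178 lower genes, there were 69 and 70 at 2-fold or more, 100 and 59 without the filter, 170 higher without chromosome 16, and 113 to 204 higher and 78 to 136 lower when a library was left out. With the replicate number as a block there were 157 and 104. The same-numbered libraries' differences correlated at -0.095 across genes, which gives no sign of a block over all genes. It cannot exclude one in some genes. Pja1 split by replicate number in the same direction in both groups, while some other genes split in opposite directions. The estimated correlation left 0 of 14 lists, where the test has 2 residual degrees of freedom. The estimate was 0.0129 for p53 targets, near the preset 0.01. It was -0.0402, -0.0416 and -0.0364 for fatty acid synthesis, NF-kB and ERK feedback genes. In these lists such estimates argue against correlation between members as the cause of the loss. Where estimates were higher, such as 0.725 for proteasome subunits, correlation and the few degrees of freedom cannot be told apart. Stricter filtering, another pseudocount, centring (largest shift 0.00749), voom, the length and GC trend and removal of overlapping-exon genes left 268 to 334 higher and 157 to 219 lower genes and 11 to 14 lists. Without overlapping-exon genes the ERK feedback list lost its call (median -0.24 against -0.31), and the mitochondrial and class I lists had too few members to test.

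Reversals were seen only in uncalled genes. Pja1 was 0.00737 with voom and ran from -0.92 to 0.92 when a library was left out. P2rx5 ran from -0.373 to 0.0505, Col1a2 from -0.142 to 0.00623 and Ssrp1 from -0.0611 to 0.0268. Of 91 called named genes 33 passed in every refit, the fits without chromosome 16 or overlapping-exon genes left aside. The cause was not tested for the others. Reads per gene limit P2rx3 (109 and 57 reads) and Cyp3a41a (1 read in induced cells). The count models named in the design for plain counts were not run, and voom on the recovered reads took their place. Alternatives on a test table of the submitters did not apply to this table.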

Other observations

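The tests of scaling, copy gain and gene order on chromosome 16, of counting error and of overlap without protocadherins were chosen after the result was seen. Some groups had no part in the account above. Glycolysis and hypoxia genes did not pass as a list (29 tested, adjusted p = 0.896), with Ndrg1, a hypoxia-responsive gene, falling from 7496 ± 402 to 5344 ± 412 and the collagen prolyl hydroxylase gene P4ha2 from 6479 ± 18.8 to 4868 ± 164 (limma adjusted p = 0.0378 and 0.0299). In the unfolded protein response (23 tested, list adjusted p = 0.896) Sel1l, of the degradation complex of the endoplasmic reticulum, fell by 0.44 on the log2 scale and the chaperone gene Dnajb11, which lies in the run on chromosome 16, rose 1.32-fold. Jag1, a Notch ligand gene, fell from 301 ± 13.4 to 146 ± 12.6 (limma adjusted p = 0.0288), and Dlk1, an imprinted gene, from 184 ± 6.15 to 70.9 ± 20.3. The prolactin-family genes Prl2c2 and Prl2c3 rose 2.52-fold and 2.26-fold, with close copies that can share reads and controls far apart (SD 1303 and 520). Nuclear respiratory chain genes, apoptosis regulators and cytosolic heat shock proteins had 0 called members of 39, 27 and 17. Leaving out a single library ended the calls of Ndrg1, P4ha2, Sel1l and Dnajb11 (adjusted p up to 0.118, 0.124, 0.0971 and 0.151) and of Jag1 and Dlk1 (up to 0.0945 and 0.126). Those of Prl2c2 and Prl2c3 ended that way and without the filter (up to 0.0890 and 0.0989). The exons of Ndrg1 overlap another gene.

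Genes of a run on chromosome 16 were higher in induced cells, 291 of 327 (89.0%) above 0, and both induced libraries showed it against the mean of the controls (medians 0.37 and 0.39), while the controls differed by 0.00. The tested genes of the other chromosomes had a median of -0.00295. Scaling of the libraries already sets such a median near 0, so this test cannot decide on scaling. A step per library moves all genes alike, so it could not by itself set the run apart from the rest. Gene length or GC content is argued against by a median of the run of 0.369 after that trend was removed. Chance order of genes is argued against by a permutation p of 0.000999 (0.001), the smallest that 1000 shuffles can give. A candidate explanation is a gain of copies of the run in the induced cells: when its bounds were set on every other gene, 88.9% of the genes left out were above 0, although the shift was uneven along the run (running median 0.23 near Cpped1 and 0.56 near Cd80, positions chosen after their values were seen), so a gain of 1 size over all of it is not shown. Copy number was not measured here, the copy gain is a hypothesis found and tested on the same data, and regional regulation by Pja2 induction and a difference between separate cell lines were not tested and stay open.

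Other runs marked against the same shuffles had smaller shifts. They held 178 of 1055 tested genes on chromosome 11 (median -0.22) and 261 of 458 on chromosome 19 (0.15). On chromosome 10 the run took in 617 of 639 tested genes, nearly the whole chromosome, with a median of -0.09. Each of these had a permutation p of 0.001. A run of 109 of 892 genes on chromosome 5, with a median of 0.10, had a permutation p of 0.045. In all, 5 of 20 chromosomes searched had a permutation p under 0.05.

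In 75 genes the libraries of a group differed by at least 2 on the log2 scale, such as Pcdhga2 (4142 and 7.37 in the controls) and Tagap (220 and 0 in the induced cells), both chosen after their values were seen. Counting error at low depth is argued against, since exact binomial splits of the reads gave 0.187 such genes expected among all those tested. Reads shared with an overlapping gene may account for many of them: 70.7% had overlapping exons against 35.3% of 750 genes of like expression (odds ratio 4.41, Fisher's exact p = 3.89e-09). Without 9 clustered protocadherins, which share exons with one another, the odds ratio was 3.90 (Fisher's exact p = 2.8e-07). The 22 genes without overlapping exons stay unexplained, no biological explanation was tested, and 2 of the 75 were called between the groups.

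Small shifts marked 6 of the lists past the set test, with medians within 0.2 of 0. Gene length or GC content is argued against as their whole cause, since 100% of them kept the call and the sign after that trend was removed. With an estimated correlation 0 of the 14 lists kept the call, and lists with an estimate near 0 lost it too, so that loss does not separate coordinated variation between libraries from an effect of Pja2 induction. Both stay open.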
